A study of Ovis aries with 8 samples.

How the data were processed

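Gene expression was measured by RNA sequencing of the mediobasal hypothalamus of adult ewes in 2 groups, food-restricted and well fed. Per the labels, RNA was extracted from each ewe with TriReagent, equal amounts from 15 ewes were mixed at random into each of 4 pools per group, and stranded mRNA libraries were built with the TruSeq kit. The 4 pools of 15 add up to the 60 ewes of a group, and the labels do not say whether an ewe entered more than 1 pool. The spread between pools is that between mixes of 15 ewes. The experiment was run in 2 consecutive years, and the labels give no year for a pool.

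The deposited values are raw read counts per gene in 1 table with 1 column per pool, per the file headers. Per the submitters' processing notes, bcl2fastq 2.20, FastQC, TopHat2 2.1.1, Bowtie2 2.3.5.1, SAMtools 1.9 and featureCounts 2.0.0 were used, with no order given. The genome build, the annotation release, the strand setting of the counting and the treatment of reads shared by several genes are not given in the sources used here. Genes that overlap others or have near-identical copies are therefore uncertain, and no coordinates are printed.

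The table lists 33609 genes by NCBI gene ID and symbol, of which 10254 had 0 counts in all pools. Of the IDs, 28100 (83.6%) were found in a RefSeq gene table of the sheep assembly ARS-UI_Ramb_v3.0, which was used for names only and replaced 471 LOC names by current symbols, ACADM among them. Total counts in food-restricted pools 1 to 4 were 42764458, 42964514, 42547151 and 41261774, and in well-fed pools 1 to 4 they were 44855182, 38257725, 48125991 and 36192025. A count of 0 allows up to 3 counts, and this limit covers counting error only. Pairs of pools of the same group differed by more than sampling noise (chi-square per degree of freedom between 25.1 and 169), so no 2 columns were taken for the same library. This does not show that the pools are independent, and they are counted as replicates on the word of the labels.

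Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 18193, and scaled by TMM. The quasi-likelihood F test (glmQLFit, glmQLFTest) compared food-restricted with well-fed pools with no covariate, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05 on the adjusted p. Log2 fold changes are food-restricted minus well fed, and their SE is the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled, as mean ± SD over the pools. The common biological coefficient of variation was 28.3%. Single genes also had an exact two-sided permutation test on log2 CPM, run in R. Python 3.11.15 was used to read the counts and draw the figures.

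Before the data were examined, 42 gene lists with 720 members were fixed, of which 37 members had no row of their own. Sets were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for the 41 lists with at least 5 tested genes (25 pathway and 16 cell type lists), with adjustment over those lists. The test was run again with the correlation estimated from each list, and with fry. Some genes stand in more than 1 list. Also fixed before were the design, the alternatives and the rule for naming genes. The rule named 17 genes whatever their result, the called genes with the largest changes or the smallest p, and up to 4 members with the smallest p of each list that was called or held a called gene. The 20 genes with symbols and the smallest p, except those the rule already named, and any other gene said to be so, were chosen after their values were seen.

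The alternatives were size factors of the DESeq2 kind (RLE), upper-quartile scaling, library totals alone, no low-count filter, a filter of at least 1 CPM in 4 pools, the replicate number as a block, each pool left out in turn, robust edgeR, DESeq2 1.42.0, limma voom with and without quality weights, and 1 surrogate variable from svaseq (sva 3.50.0). Chosen after seeing the data were 2 surrogate variables, 1 surrogate variable in the set test, both food-restricted pools 1 and 3 left out, and the side of each pool on the first principal component as a block. All 35 splits of the 8 pools into 4 and 4 were also fitted. Another test of the split of the pools, chosen after its result was seen, is not reported here.

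The gene test was tested on simulated data in 5 runs of counts drawn for the 18193 genes, with 200 genes changed in each. It recovered 9.6% of genes changed 1.5-fold, 53.6% changed 2-fold, 84.0% changed 3-fold and 93.6% changed 4-fold, and called 50 of 89965 unchanged genes. Those 50 false calls stood beside 24, 134, 210 and 233 true calls at these 4 folds. A list shifted by -0.2 on the log2 scale was called by camera in 4 of 5 runs, and 0 of 200 tests of other lists gave a call. In that simulation the genes were drawn independently of each other.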

Results

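The effect of food restriction on the transcriptome of the mediobasal hypothalamus was examined in adult Ile-de-France ewes. This block of tissue at the base of the brain holds the arcuate nucleus, whose neurons regulate appetite, reproduction and growth hormone release. RNA from 60 food-restricted and 60 well-fed ewes, 30 of each in each of 2 years, was combined into 8 sequencing pools of 15 ewes. Each group thus gave 4 pools, and n counts pools throughout. Total counts were between 41261774 and 42964514 in the food-restricted pools and between 36192025 and 48125991 in the well-fed pools. Of 33609 genes listed, 18193 had enough reads to be tested. The first principal component of log2 CPM (read counts scaled to the size of each library) held 34.7% of the variance and parted the pools across the groups, with 2 food-restricted and 2 well-fed pools on each side of 0. The year of the ewes in a pool is not given in the labels.

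**Figure D1:**
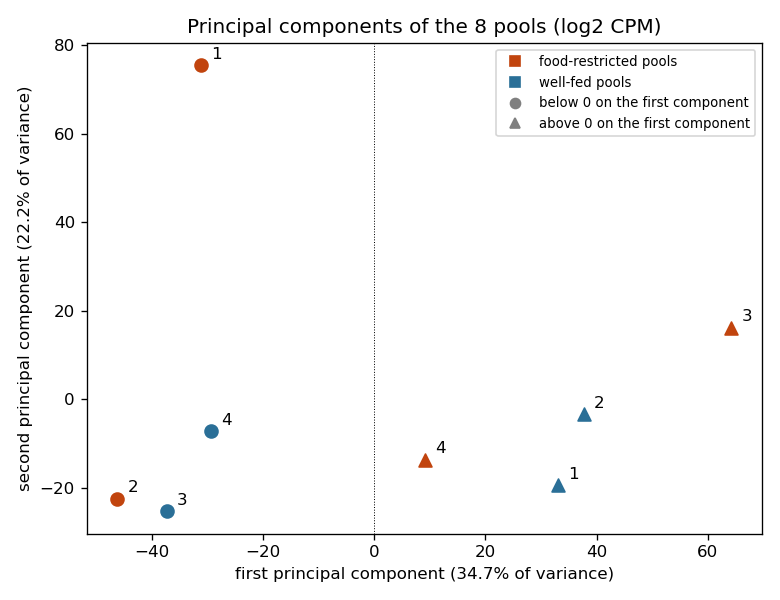
Principal components of log2 CPM in the 8 pools, with the first component on the horizontal axis (34.7% of variance) and the second on the vertical axis (22.2%). Colour gives the group, the number beside each point is the replicate number, and circles and triangles mark pools below and above 0 on the first component, where each side holds 2 pools of each group.

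The transcript of AGRP (gene ID 443269), the agouti-related peptide of arcuate neurons that stimulate feeding, rose with food restriction. AGRP was at 155 ± 25.9 CPM in food-restricted pools and 50.7 ± 10.1 CPM in well-fed pools (mean ± SD, n = 4 each), a log2 fold change of 1.61 (SE 0.17) or 3.06-fold. All 4 food-restricted pools lay above all 4 well-fed pools, and AGRP was the 1 gene of 18193 that passed the test (edgeR quasi-likelihood, adjusted p = 0.0296). NPY (gene ID 443508), which the same neurons release, was at 141 ± 46.4 CPM against 59.8 ± 29.4 CPM (SD, n = 4 each), a log2 fold change of 1.24 (SE 0.35) or 2.36-fold. NPY did not pass over all genes (edgeR adjusted p = 1) and did among the 10 tested appetite-stimulating peptides (edgeR adjusted p = 0.0256 when adjusted over the list alone). Its pools did not overlap either, and an exact two-sided permutation test on log2 CPM gave p = 0.0286 for each of the 2 genes, the smallest p that 4 pools against 4 allow. Within the 4 pools below 0 on the first principal component, AGRP was 2.77-fold and NPY 2.02-fold higher with food restriction. Within the 4 pools above 0, AGRP was 3.41-fold and NPY 3.11-fold higher. With these sides as a block, the edgeR adjusted p of NPY was 0.00404, where its alternatives ranged from 0.00404 to 1. Leaving out any 1 of the 8 pools ended the call of AGRP (edgeR adjusted p between 0.0706 and 0.215), while its log2 fold change stayed between 1.49 and 1.73. Of the 14 other alternatives, 12 called AGRP. The call was lost with the replicate number as a block and without both food-restricted pools 1 and 3.

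**Figure D2:**
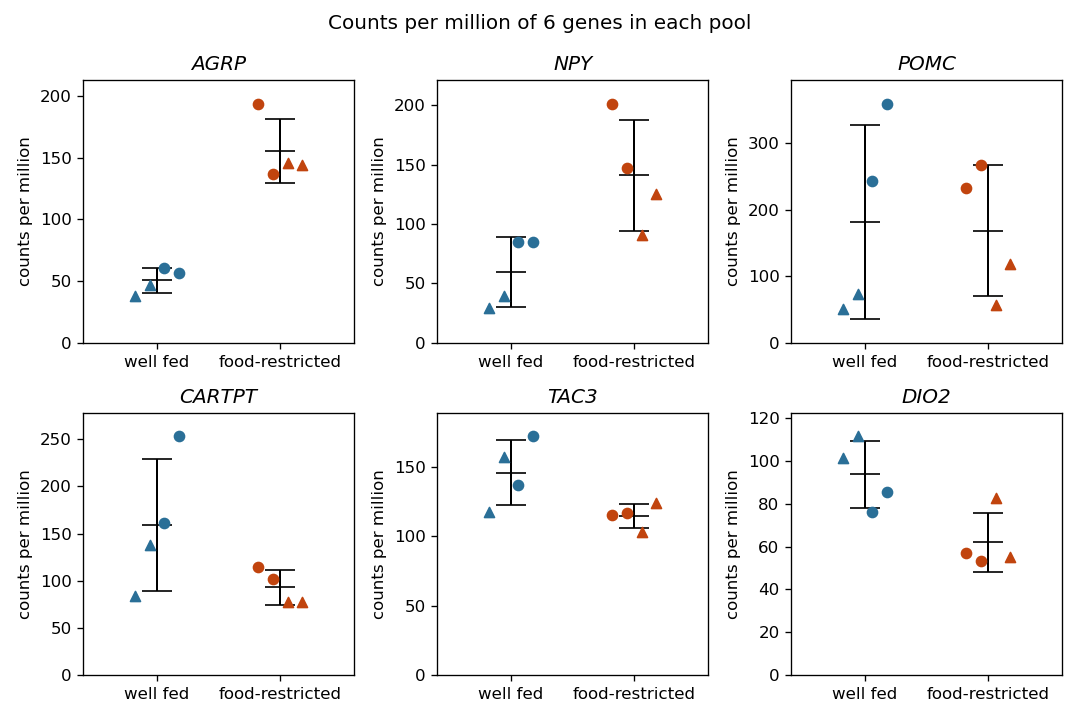
CPM of AGRP, NPY, POMC, CARTPT, TAC3 and DIO2 in each pool (vertical axis, from 0), by group on the horizontal axis. Circles are pools below 0 and triangles pools above 0 on the first principal component, long bars give the mean and the end bars 1 SD on each side (n = 4). The food-restricted pools of AGRP, between 137 and 193 CPM, lie above the well-fed pools, between 38.2 and 60.7 CPM.

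No gene was called lower in the food-restricted pools by edgeR without a covariate. With the side of the first principal component as a block edgeR called 4 genes lower (HSPA6, ARRDC2, ZBTB16 and FKBP5), with 1 surrogate variable it called these and DIO2, and with 2 surrogate variables HSPA6 and ARRDC2. Without a covariate, at an unadjusted p under 0.05, 122 genes were higher and 187 were lower, 309 together, where 910 would be met by chance. limma voom called AGRP and no gene lower, and DESeq2 called AGRP and 4 genes lower. The last 4 were ZBTB16, which the naming rule held, and HSPA6, ARRDC2 and the uncharacterised LOC114117986, which were named after their values were seen. The groups did not overlap in 1.6% of the tested genes, where chance gives 2.86%.

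The other feeding peptides gave no call over all genes. Of the 10 tested members of the appetite-stimulating list, AGRP rose and 9 did not pass, among them PMCH (melanin-concentrating hormone), with a log2 fold change of 0.11 (SE 0.24), and HCRT (orexin), at -0.13 (SE 0.56). The list had a median log2 fold change of 0.05 and did not pass as a set (camera adjusted p = 0.0729; adjusted p = 0.682 with an estimated correlation). It was called higher without food-restricted pool 3 (camera adjusted p = 0.0266), without well-fed pool 3 (0.0452) and with upper-quartile scaling (0.0481), and in mixed fry (0.0356), which does not ask for one direction. NPW, a low peptide transcript, was at 1.08 ± 1.24 CPM against 0.743 ± 0.724 CPM (SD, n = 4 each). None of the 14 tested appetite-reducing peptides passed, over all genes or adjusted over the list alone, and the list did not move as a set (median 0.01, camera adjusted p = 0.858). POMC, the precursor of the melanocortins that reduce feeding, was at 169 ± 98.1 CPM against 182 ± 146 CPM (SD, n = 4 each), with a log2 fold change of -0.11 (SE 0.61). It was lower in each group in the pools above 0 on the first principal component than in those below 0. CARTPT, its partner peptide, was at 93.3 ± 18.6 CPM against 159 ± 70.4 CPM (log2 fold change -0.77, SE 0.28), with overlapping pools. CRH was at 4.12 ± 1.81 CPM against 4.44 ± 2.02 CPM, and TRH at 31.5 ± 10.8 CPM against 28.9 ± 4.09 CPM. The leptin receptor LEPR was near 1 CPM, at 0.691 ± 0.278 against 0.650 ± 0.501 CPM, with an SE of 0.62 on its log2 fold change of 0.09. None of the 21 tested receptors for metabolic hormones and feeding peptides passed, and 9 were higher and 12 lower (median -0.03, camera adjusted p = 0.781). The 16 genes of leptin and insulin signalling had a median of 0.00 (camera adjusted p = 0.858).

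Among genes of the reproductive axis, 0 of 13 tested passed by edgeR over all genes or over the list alone, and 1 had an unadjusted p under 0.05 (list median -0.03, camera adjusted p = 0.685). That gene was TAC3, the neurokinin B of arcuate kisspeptin neurons, at 115 ± 8.78 CPM against 146 ± 23.6 CPM (SD, n = 4 each), a log2 fold change of -0.35 (SE 0.13). KISS1 (kisspeptin) was at 4.09 ± 1.56 against 5.13 ± 2.01 CPM and PDYN (dynorphin) at 26.9 ± 8.64 against 31.1 ± 8.62 CPM. GNRH1, the releasing hormone of the gonadal axis, was at 5.78 ± 0.807 against 4.11 ± 0.989 CPM, with a log2 fold change of 0.49 (SE 0.22). In the thyroid hormone list, DIO2, which activates thyroid hormone in tanycytes, was at 62.1 ± 13.8 CPM against 93.7 ± 15.7 CPM (log2 fold change -0.59, SE 0.17). It did not pass over all genes (edgeR adjusted p = 1) or within its list (edgeR adjusted p = 0.079 when adjusted over the list alone), and passed with 1 surrogate variable in the fit (edgeR adjusted p = 0.0499, the lowest among its alternatives, which ranged up to 1). DIO3, which inactivates the hormone, was at 1.36 ± 0.705 against 1.54 ± 0.802 CPM. The 14 tested thyroid genes did not move as a set (median -0.07, camera adjusted p = 0.411). The pars tuberalis hormone genes TSHB and CGA were at 9.42 ± 4.71 against 13.6 ± 4.37 CPM and at 1166 ± 272 against 1187 ± 259 CPM. In the somatotropic list, GHRH was at 20.4 ± 3.84 against 19.2 ± 3.16 CPM, and the 13 tested genes had a median of 0.04 (camera adjusted p = 0.748). SST was listed at 0 in all 8 pools, for which 3 counts, the limit that a count of 0 allows, are between 0.0623 and 0.0829 CPM. Its row can be a failure of read assignment, and no fold is given.

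Of 41 gene lists tested as sets with camera at a preset correlation, 7 were lower in the food-restricted pools and 0 were higher. None of the 7 kept its call with a correlation estimated from each list (lowest adjusted p = 0.126 with an estimated correlation). The estimates for the glucocorticoid-induced (-0.006) and amino acid response (-0.052) lists lay below the preset 0.01. For these lists the loss thus does not come from a higher correlation between genes. Directional fry called 3 of the 7: heat shock, glucocorticoid-induced and amino acid response (fry adjusted p = 0.0431 each). With other scalings and the preset correlation, camera gave 7 lower and 1 higher (size factors of the DESeq2 kind, or library totals). With the upper quartile it gave 7 lower and 2 higher. The lists called higher were mature oligodendrocytes and, with the upper quartile, also appetite-stimulating peptides. The cytosolic heat shock list, of chaperones and co-chaperones, had all 16 tested members lower (median log2 fold change -0.20, camera adjusted p = 4.94e-06). The call was lost with a correlation estimated from the list (adjusted p = 0.126 with an estimated correlation). DNAJB1 was at 112 ± 6.5 CPM against 138 ± 9.97 CPM (log2 fold change -0.31, SE 0.10) and DNAJA1 at 185 ± 7.20 CPM against 215 ± 6.59 CPM (-0.22, SE 0.09), both without overlap between the groups. STIP1 (-0.24, SE 0.11) and FKBP4 (-0.22, SE 0.10) were the next smallest in p. No single member of the list passed, over all genes or adjusted over the list alone.

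The glucocorticoid-induced list had 11 of 17 tested members lower (median -0.18, camera adjusted p = 0.0021), a call that was lost with an estimated correlation (adjusted p = 0.126 with an estimated correlation). Of these members 2 fell when adjusted over the list alone, while 0 passed over all genes without a covariate. ZBTB16, a transcription factor, was at 48.1 ± 5.98 CPM against 82.1 ± 12.2 CPM (SD, n = 4 each), with a log2 fold change of -0.77 (SE 0.14) and an edgeR adjusted p of 0.925 over all genes and 0.00346 over the list alone. FKBP5, a co-chaperone of the glucocorticoid receptor, was at 64.5 ± 10.1 CPM against 101 ± 8.14 CPM (-0.65, SE 0.13), with an edgeR adjusted p of 1 over all genes and 0.00407 over the list alone. Both passed over all genes with the side of the first principal component as a block (edgeR adjusted p = 0.0487 each) and with 1 surrogate variable (0.0253 each), and ZBTB16 in DESeq2 (adjusted p = 0.0133). In both genes all food-restricted pools lay below all well-fed pools. CDKN1A (-0.40, SE 0.13) and PDK4 (-0.38, SE 0.16) had the next smallest p. Other members went the other way, among them NR3C1, the glucocorticoid receptor (0.15, SE 0.14).

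**Figure D3:**
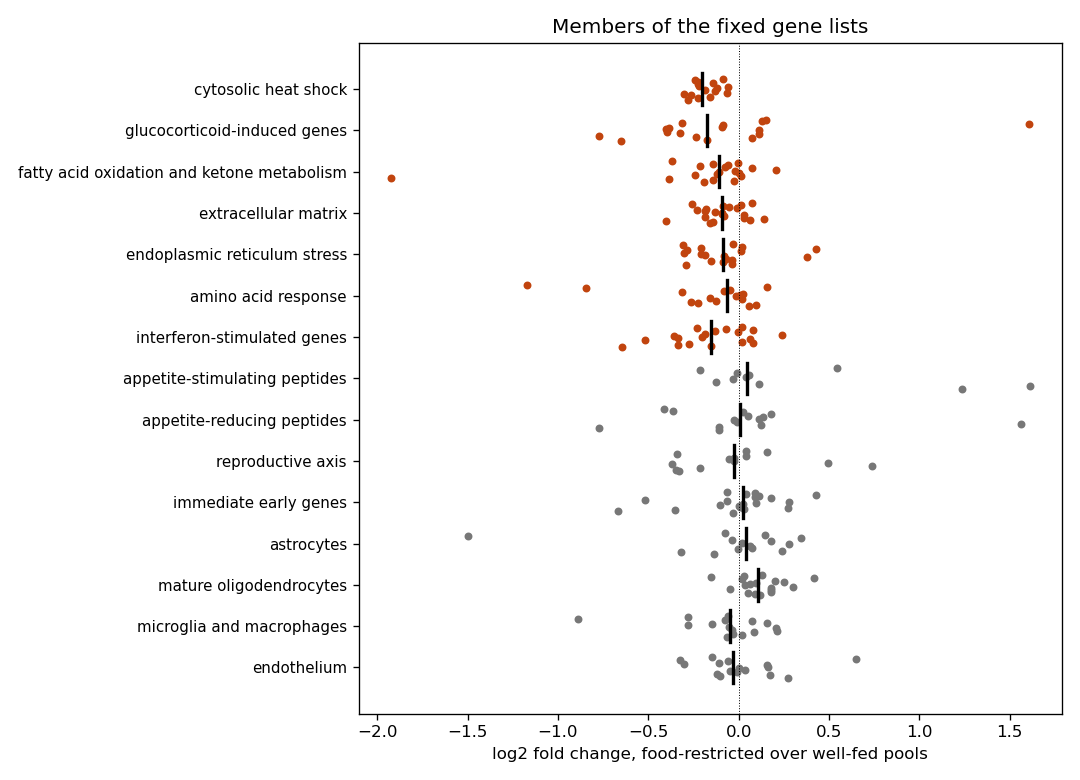
Log2 fold change (food-restricted over well-fed, horizontal axis) of each tested member of 15 gene lists (vertical axis), with a vertical bar at each list's median. Orange lists were lower as sets by camera at the preset correlation, a call that none of them kept with an estimated correlation, and grey lists were not called. All 16 members of the cytosolic heat shock list lie below 0.

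The remaining 5 lists called lower held no member that passed, over all genes or adjusted over the list alone, and none of them kept its call with an estimated correlation. Fatty acid oxidation and ketone metabolism had 15 of 19 members lower (median -0.11, camera adjusted p = 0.0144; adjusted p = 0.267 with an estimated correlation), with ACADVL at -0.24 (SE 0.10) and PLIN2, a lipid droplet protein, at -0.37 (SE 0.19). ACADM in this list was at most 0.813 CPM in any pool, with 0 counts in food-restricted pool 3, and its fold is not reported. Extracellular matrix had 15 of 21 members lower (median -0.09, camera adjusted p = 0.0203; adjusted p = 0.267 with an estimated correlation), with the collagen gene COL3A1 at -0.41 (SE 0.14), SPARC at -0.18 (SE 0.08), LAMC1 at -0.23 (SE 0.12) and FBN1 at -0.26 (SE 0.13). Endoplasmic reticulum stress had 14 of 18 lower (median -0.08, camera adjusted p = 0.0305; adjusted p = 0.677 with an estimated correlation). Its chaperones CALR (-0.31, SE 0.09), HYOU1 (-0.31, SE 0.12) and HSPA5 (-0.29, SE 0.13) were lower in the fit and ATF3, a stress-induced transcription factor, was higher (0.43, SE 0.24). The amino acid response had 10 of 16 lower (median -0.07, camera adjusted p = 0.0472; adjusted p = 0.267 with an estimated correlation), with MTHFD2 at -0.84 (SE 0.26), SESN2 at -0.26 (SE 0.14), DDIT4 at -0.31 (SE 0.18) and CEBPB, under 2 CPM in all pools, at -1.17 (SE 0.67). Interferon-stimulated genes had 13 of 19 lower (median -0.15, camera adjusted p = 0.0472; adjusted p = 0.816 with an estimated correlation), with ISG15 at -0.64 (SE 0.27), MX2 at -0.34 (SE 0.16), IFIH1 at -0.36 (SE 0.24) and IRF9 at -0.19 (SE 0.13). All 5 lists lost their calls without food-restricted pool 2 (camera adjusted p between 0.0572 and 0.381) and without well-fed pool 2 (between 0.091 and 0.609). Endoplasmic reticulum stress was also lost without food-restricted pool 4 (0.206) or well-fed pool 4 (0.132), extracellular matrix without food-restricted pool 3 (0.291) or well-fed pool 3 (0.0804), interferon-stimulated genes without food-restricted pool 1 (0.389) or 4 (0.206), and the amino acid response without food-restricted pool 3 (0.214) or 4 (0.16) or well-fed pool 3 (0.093) or 4 (0.121).

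None of the 16 cell type lists tested was called, and their medians lay between -0.11 and 0.17. Mature oligodendrocytes came closest, with 16 of 18 markers higher in the food-restricted pools (median 0.11, camera adjusted p = 0.0519), and passed under each of the other 3 scalings (camera adjusted p between 0.0481 and 0.0498). With an estimated correlation this list had an adjusted p of 0.816. At the preset correlation it also passed with the side of the first principal component as a block (camera adjusted p = 0.0126), with 1 surrogate variable (0.0384), and without food-restricted pool 4 (0.0193), well-fed pool 1 (0.0252) or well-fed pool 3 (0.00577), and it was not called without any of the other 5 pools. All 8 tested dopamine neuron markers were lower (median -0.11, camera adjusted p = 0.217). Among the 12 tested arcuate and ventromedial genes AGRP rose and 11 did not pass, such as NKX2-1 (1.11-fold) and TBX3 (1.09-fold). The median of that list was -0.07 although camera's direction was up (adjusted p = 0.65). The medians were 0.09 for GABA and glutamate neurons, 0.06 for neurons in general, 0.06 for tanycytes, 0.03 for ependymal cells, 0.04 for choroid plexus, 0.04 for astrocytes and 0.03 for oligodendrocyte progenitors. They were -0.05 for microglia and macrophages, -0.03 for endothelium, -0.01 for pericytes, smooth muscle and meninges, 0.17 for posterior pituitary and magnocellular neurons, and 0.06 for the neighbouring suprachiasmatic, lateral and thalamic areas. Camera adjusted p for these lists was 0.56 or more. Camera's direction was down for choroid plexus and oligodendrocyte progenitors, against their medians, and the astrocyte mean was -0.05, against its median. In the pituitary list (17 tested, median 0.01, camera adjusted p = 0.65), EYA3, a pars tuberalis cofactor, was at 162 ± 11.6 against 120 ± 13.4 CPM (0.43, SE 0.11) and passed within the list (edgeR adjusted p = 0.0484 when adjusted over the list alone) but not over all genes. Of the red blood cell markers 3 were tested, too few for a set test.

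The other pathway lists were not called. Immediate early genes had 12 of 20 members higher and a median of 0.03, with camera's direction down (adjusted p = 0.685). FOSB (-0.67, SE 0.15, edgeR adjusted p = 0.0173) and NR4A3 (-0.52, SE 0.14, edgeR adjusted p = 0.0316) fell when adjusted over the list alone and did not pass over all genes, and FOS was at -0.03 (SE 0.16). Retinoic acid genes had a median of 0.06 (camera adjusted p = 0.781), cholesterol synthesis and uptake 0.02 (0.883), fatty acid synthesis -0.01 (0.914), glycolysis and glucose transport -0.04 (0.657) and the nuclear genes of the respiratory chain 0.03 (0.861). The circadian clock had a median of -0.01 (camera adjusted p = 0.657), antigen presentation -0.02 (0.411), autophagy and lysosome -0.02 (0.891), axon growth and synapse -0.01 (0.861) and cell division 0.03 (0.685), the last with camera's direction down. In simulated counts, the test recovered 84.0% of 3-fold changes, 53.6% of 2-fold changes and 9.6% of 1.5-fold changes. Changes of the last size were thus mostly missed. Each simulated run held 200 changed genes, and all genes were drawn independently of each other. The adjusted threshold is easier to reach with that many changed genes than with the 1 gene called in the real pools. The shares recovered therefore do not give the power in the real pools, which can be lower.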

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

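In 126 groups of 4 pools (each tested named gene in each feeding group), 6 held a pool that stood apart by Dixon's ratio, its gap to the nearest other pool over the group's whole range set against the critical value for 4 samples. Chance gives about 6.3 such groups in 126, so the number of them is what chance gives. No test was run on these values beyond the ratio, and no explanation was tested.

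Among the genes named before the data were examined, GNRH1 was lowest in food-restricted pool 2, at 4.57 CPM, while the other food-restricted pools were between 6.07 and 6.30 CPM (ratio 0.881). DIO2 was highest in food-restricted pool 3, at 82.6 CPM against 53.4 to 57.0 CPM in the other 3 (ratio 0.849), and this pool lies within the range of the well-fed pools, 76.2 to 111 CPM. Among members of the called lists, CDKN1A was lowest in well-fed pool 1, at 19.7 CPM against 23.3 to 23.5 CPM (ratio 0.954), and IRF9 was highest in well-fed pool 2, at 81.3 CPM against 67.4 to 68.6 CPM (ratio 0.91). Among genes chosen after their values were seen, RNF113A was highest in food-restricted pool 4, at 3.61 CPM against 2.27 to 2.38 CPM (ratio 0.899), and NR4A3 was lowest in well-fed pool 3, at 18.9 CPM against 23.8 to 24.9 CPM (ratio 0.844).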

How the results depend on the processing

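Chosen after seeing the data were the fits with 2 surrogate variables, with 1 surrogate variable in the set test, without both food-restricted pools 1 and 3, and with the side of the first principal component as a block. The gene count was 1 (AGRP) in the fit as designed, with RLE, upper-quartile or library-total scaling, with either other filter, with robust edgeR and with both forms of voom. It was 8 with 1 surrogate variable (3 higher, 5 lower: AGRP, NPY and NOTCH1 higher, HSPA6, ARRDC2, DIO2, ZBTB16 and FKBP5 lower), 5 with 2 surrogate variables (3 higher, 2 lower), 6 with the side as a block (2 higher, 4 lower), 5 in DESeq2 (1 higher, 4 lower), and 0 without pools 1 and 3. AGRP was among the calls in each of these fits but the last, where its log2 fold change was 1.47. Leaving out each pool in turn, which leaves fewer pools in each fit, gave 0 genes all 8 times. The replicate numbers did not pair the pools: deviations of same-numbered pools correlated at -0.21, -0.42, -0.35 and -0.21, and no pool correlated best with its own number. With the replicate number as a block, 0 genes and 3 lists were called, and AGRP had a log2 fold change of 1.62.

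The count of lists, 7 as designed, was between 6 and 9 with the other scalings, the 1 CPM filter, 1 surrogate variable and the side as a block. It was 2 without a filter, 4 without pools 1 and 3, 0 with an estimated correlation (5 lists at an unadjusted p under 0.05), 3 in directional fry (heat shock, glucocorticoid-induced and amino acid response), 3 in mixed fry (glucocorticoid-induced, arcuate and ventromedial, and appetite-stimulating, without heat shock, whose adjusted p was 0.138), and between 2 and 8 when each pool was left out. Heat shock and glucocorticoid-induced lists passed without each of the 8 pools in turn (highest camera adjusted p 0.00217 and 0.0405).

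Directions that reversed all belonged to genes without a call, and the cause was not tested. The log2 fold change of the gene POMC was 0.093 with the replicate block, 0.075 without pools 1 and 3, 0.11 with the side as a block and 0.096 in voom. Without pools 1 and 3, the gene GHRH was at -0.002, the gene PDYN at 0.14 and the gene DIO3 at 0.18, and GHRH was at -0.068 with 2 surrogate variables. The gene NPW was at -0.14 and -0.21 with 1 and 2 surrogate variables and -0.24 in weighted voom. With each pool left out in turn the log2 fold change lay between -0.42 and 0.46 for POMC, -0.046 and 0.19 for GHRH, -0.12 and 0.27 for TRH, -0.16 and 0.12 for CGA, -0.482 and 1.119 for NPW, -0.31 and 0.19 for CRH, -0.20 and 0.72 for LEPR, and -0.60 and 0.19 for DIO3. LEPR, NPW and DIO3 had from 3 to 115 counts per pool.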

Other observations

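Chosen only after the result was seen were the tests of pituitary tissue, arcuate tissue, glial or vascular cells, and genes of a list moving together. The tests of the splits, of the pool sides, of AGRP neuron markers and of CREB targets were set before their results were seen.

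The 20 genes with symbols and the smallest p were taken as a group after their values were seen, though the naming rule already held AGRP, ZBTB16 and FKBP5. Of the 20, AGRP passed over all genes. HSPA6, an inducible heat shock protein 70 outside the fixed heat shock list, was at 9.58 ± 0.684 CPM in food-restricted and 17.9 ± 1.37 CPM in well-fed pools (SD, n = 4 each), a log2 fold change of -0.90 (SE 0.13, edgeR adjusted p = 0.34). ARRDC2, an arrestin-domain protein, was at 17.1 ± 2.39 CPM against 31.7 ± 4.11 CPM (-0.89, SE 0.15, edgeR adjusted p = 0.661). Both were called lower in 4 of 14 alternatives, not counting the fits with 1 pool left out: DESeq2 (adjusted p = 6.14e-05 and 0.0021) and edgeR with 1 surrogate variable (0.0198 and 0.009), with 2 (0.03 and 0.00624) and with the side of the first principal component as a block (0.0294 and 0.0102). The other alternatives ranged up to 1. Also lower in the fit, with edgeR adjusted p = 1, were GEM (-0.77), VAV3 (-0.58), RNF113A (-0.96), H1-6 (-0.76), DYRK3 (-0.69), CREM (-0.45), OSBPL11 (-0.46) and ADAMTSL4 (-0.49). Higher in the fit were TBP (0.52), ID2 (0.48), RNASE6 (0.79) and FOXC1 (0.62). Of the red blood cell markers, HBB was at -2.01 (SE 0.82), AHSP at 0.296 (SE 0.576) and GYPC at 0.364 (SE 0.273). MRC1, a marker of perivascular macrophages chosen after its value was seen, was at -0.89 (SE 0.26, edgeR adjusted p = 0.0911 when adjusted over the list alone).

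CREM, NR4A3, FOSB and GEM are known to respond to cyclic AMP, which gave the hypothesis that targets of the transcription factor CREB were lower as a class. Of 19 other CREB targets 11 were higher and 8 lower, with a camera p of 0.752. Their median log2 fold change was 0.05 (SD 0.24), where the 4 genes that gave the hypothesis lay between -0.77 and -0.45, which argues against it. Some of the other targets, such as FOS, NR4A1, EGR1 and ARC, also stand in the immediate early list, so this test partly repeats that one.

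The pools parted across the groups on the first principal component. The split of the pools by their side of 0 called 3384 genes, 2527 higher and 857 lower in the pools below 0 (food-restricted 1 and 2, well-fed 3 and 4), but the sides were defined from these same values. POMC was higher in these pools by 1.88, MIF by 3.58, APOE by 1.29, AVP by 2.14 and OXT by 3.69 on the log2 scale, and AGRP by 0.26 (SE 0.42). More tissue of the pars tuberalis and pars distalis, whose markers make up the pituitary list, would have raised that list with POMC. LHB (2.015) and PITX1 (1.959) were higher by as much and members such as NR5A1 (1.311), LHX3 (0.998) and CHGA (0.507) by less. The median of the 17 tested members was 0.17 (SD 0.82), and that of the hormones CGA, PRL, GH, FSHB and TSHB was -0.06. These medians argue against more tissue of these 2 parts as the whole cause. More tissue of other parts of the pituitary was not tested and stays open. The year of the ewes, the dissection and the library batch stay open, as does GC content, which was not tested here. A different share of tissue in the block is counted as technical, and no biological explanation was tested.

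AGRP and NPY were higher in the food-restricted pools on both sides of that split. The number of genes called does not exclude chance, since 3 of the 35 splits of the 8 pools called at least 1 gene (highest other split 3384, the one by side), and 3 called at least the 8 found with 1 surrogate variable (highest other 5060, the same split). More arcuate tissue in the food-restricted pools is argued against by the other 11 arcuate and ventromedial genes, with a median of -0.10 and an SD of 0.18. That NPY missed the call may come from the spread between the sides, since with the side as a block its SE went from 0.35 to 0.16 and its edgeR adjusted p to 0.00404 (range over its alternatives 0.00404 to 1). More AGRP neurons per pool and more AGRP transcript per neuron cannot be told apart. The bound set beforehand as evidence against more neurons was a marker median more than 1 SD of the markers below AGRP. It was met, as 10 other markers had a median of 0.04 (SD 0.28). In a check that was not part of that bound, 9 of them, such as BSX (0.275, SE 0.532) and OTP (-0.035, SE 0.435), lay more than 2 combined SE below AGRP. The bound set beforehand cannot decide the question if these markers are also expressed by other neurons of the block, whose share would hide a rise. Which neurons express them was not measured here. The highest marker, ACVR1C at 0.88 (SE 0.37), lies within 2 combined SE of AGRP.

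The heat shock and glucocorticoid-induced lists were lower in the food-restricted pools at the preset correlation, calls that both lost with an estimated correlation (adjusted p = 0.126 each with an estimated correlation). For the count of 7 lists at the preset correlation, 1 of the 35 splits, the real one, gave as many, and the highest other gave 3. That is the smallest share that 35 splits allow, and the counts of genes called did not exclude chance. It argues against chance for the count of lists, and not for any 1 list, without excluding it. Each side of the first principal component held 2 food-restricted and 2 well-fed pools, so the sides are balanced over the groups. With the side as a block both lists kept a camera adjusted p under the threshold (0.00322 for the larger). A balanced block leaves the group difference in place, so this fit cannot test the side as a cause. The medians within each side can be compared. In the pools below 0 they were -0.126 for the glucocorticoid-induced and -0.135 for the heat shock list, and in those above 0 they were -0.218 and -0.18. A difference between the sides that both groups share would not lower the lists within each side. The values thus argue against such a difference as the cause for these 2 lists. Fewer oligodendrocytes are argued against by the median of their list, 0.106 (SD of its members 0.13), against -0.176 and -0.204 for the 2 lists. Fewer astrocytes, microglia or endothelial cells stay open. The medians of these lists, the lowest of which was -0.046, lie above that of the glucocorticoid-induced list by less than the SD of their members (0.45, 0.26 and 0.24). In the microglia and macrophage list 10 markers were lower in the fit, such as MRC1, and 6 were higher. Also open for the heat shock list, whose estimated correlation was 0.059, is that its genes move together between pools whatever the group. The loss of its call cannot decide this, since lists with an estimate below the preset correlation also lost theirs. Directional fry still called the heat shock list (fry adjusted p = 0.0431), and mixed fry did not (0.138). For the glucocorticoid-induced list the estimated correlation was -0.006, not above the preset 0.01. This argues against such movement as the reason for the loss of its call. A lower glucocorticoid or heat shock response with food restriction is a hypothesis that was not tested.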
